A study of Homo sapiens with 24 samples.

How the data were processed

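RNA of 24 human tissue samples was measured on Illumina bead arrays. The labels assign 3 samples to skeletal muscle, 3 to skeletal muscle next to a tumour (adjacent muscle), 8 to ERMS and 10 to alveolar rhabdomyosarcoma (ARMS). ERMS usually stands for embryonal rhabdomyosarcoma; the labels expand the letters differently, so only the letters are used here. Rhabdomyosarcoma (RMS) is a soft tissue cancer whose cells carry part of the muscle programme. Per the labels' protocols, tissue was fresh frozen, and biotin-labelled cDNA was made from 100 ng of total RNA with a mix of poly-T and random primers. The scanner, its software and the bead-level steps are not given in the sources used here.

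A pair of tables was deposited. The non-normalised table holds the deposited intensity of 48803 probes on a linear scale, with no detection p and no control probes; its values run from 29.1 to 37540, and the array medians from 60.77 to 83.17. No value lies below 0. The series' value table holds intensity values of 48802 probes processed by the authors. Its columns share the same sorted values to within 0.513% and a median of 70.35, which is what quantile normalisation gives, and they lie within 0.509% of the geometric means of the sorted non-normalised columns, so no background was subtracted. Each of the 24 columns of the value table matched 1 non-normalised column by rank order, with a rank correlation of 1. Among the non-normalised columns, 2 share a name; both belong to ARMS, and the match by rank tells them apart. The values of the value table are linear and uncentred, which leaves neither scale nor direction open; the software that made them is not given in the sources used here.

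From the non-normalised intensities, background was corrected with limma's normexp method (offset 50), the 24 arrays were quantile normalised, and log2 was taken. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used; figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probes were named from the platform annotation supplied with the data. It lists 28111 of the probes, 28098 with 1 gene symbol and 13 with several, and does not list 20692, which stay unnamed here. Of the named probes, 28059 matched a gene table by gene number, and 0 symbols needed an update. XIST and Y-linked genes (123 probes) were left out. A gene was represented by its probe with the highest mean over all arrays, which gave 18775 genes, 6100 of them with several probes. No coordinates are given, since the files name no genome build.

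Arrays fell into sets of near-identical profiles. The 20 pairs inside a set correlated at 0.9833 to 0.9963 over the 10849 probes brighter than 200 on some array. At most 0.424% of the 7778 genes brighter than 200 on some array differed by over 2-fold in such a pair. The 254 pairs of different profiles correlated at 0.5826 to 0.9605, with 3.6% to 44.7% of those genes over 2-fold apart. Arrays of 1 label that correlated above 0.97 were therefore averaged into 1 profile and counted as 1 replicate. The value of 0.97 was set after the gap between both kinds of pairs was seen, and the design fixed before the data were examined had counted each array as a sample. The profiles are S1 (skeletal muscle 1 to 3), A1 (adjacent muscle 1), A2 (adjacent muscle 2 and 3), E1 (ERMS 1 to 4), E2 (ERMS 5), E3 (ERMS 6 and 8), E4 (ERMS 7), R1 (ARMS 1 and 2 and both arrays of the shared name), R2 (ARMS 5), R3 (ARMS 6), R4 (ARMS 7 to 9) and R5 (ARMS 10). This left 12 profiles: 1 of skeletal muscle, 2 of adjacent muscle, 4 of ERMS and 5 of ARMS. E3 and R5 also correlated above that value (0.9781 and 0.9788), under different labels, and were kept as separate profiles.

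All other choices named here as planned were made before the data were examined. Each comparison was fitted with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). RMS versus muscle used all 12 profiles with 4 group means, and set the mean of the ERMS and ARMS means against the mean of both muscle means, so S1 carries as much weight as A1 and A2 together. ARMS versus ERMS used the 9 tumour profiles. Adjacent versus skeletal muscle used the 3 muscle profiles and has almost no degrees of freedom (2.65, residual plus prior). Means given for muscle and RMS are such means of group means; SDs are over profiles. A total of 41 gene lists, written from general knowledge before the data were examined, were tested with limma's camera at the preset correlation of 0.01, again with an estimated correlation, and with fry. Camera asks whether a list moves relative to the other genes; fry asks whether its genes move, on balance, one way. The level of a list in a profile is the mean over its genes of the log2 value minus that gene's mean over the profiles.

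The genes named were chosen by a rule fixed in advance. For RMS versus muscle it takes the 8 largest increases and 8 largest decreases among genes past the threshold in which every tumour lies on one side of every muscle sample, for each list past camera the 2 members with the largest statistic among those past the threshold, and in any case MYOD1, MYOG, MYF5, MYF6, PAX3, PAX7, MYH3, MYH2, CKM, IGF2, CCND2, CDK4, TOP2A and EZH2. For ARMS versus ERMS it takes the 8 largest changes in each direction past the threshold, list members as above, and in any case TFAP2B, CDH3, OLIG2, NOS1, PIPOX, FGFR4, ALK, MYCN, CNR1, HMGA2, EGFR, FBN2, MYOG, MYOD1, PAX3, PAX7, FOXO1, CCND2 and CDK4. For adjacent versus skeletal muscle it takes only genes past the threshold. Further genes are named as chosen after their values were seen. A single gene that the rule picked is left out of the text, and of the counts of named genes kept, because a common inherited variant can set its level.

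The steps were tested on simulated data with 18775 genes and known changes. For RMS versus muscle, 62%, 86.8%, 94% and 97.2% of genes changed by 1, 2, 3 and 4 log2 units were called, with 12 false calls per run. For ARMS versus ERMS these shares were 63.2%, 88.4%, 97.6% and 98.4%, with 12.4 false calls per run. For adjacent versus skeletal muscle limma called 0% at each of these sizes, so its gene counts cannot show an absence of change. The changed genes were drawn at random from all genes, each with its own spread, so the shares are averages. They do not hold for genes of wide spread, such as TFAP2B (SE 1.34) and PIPOX (SE 0.925) in ARMS versus ERMS. For such genes a missing call does not show an absence of change. The list that was changed was called in 5 of 5 runs for each comparison, and over the 5 runs 0, 1 and 1 other lists were called. The simulated genes were drawn independently, which suits camera's preset correlation. In the measured data the estimated correlation in RMS versus muscle was 0.606 for adult sarcomere and 0.451 for mitosis. The runs therefore do not show how often camera calls unchanged lists of correlated genes.

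Alternatives planned in advance were no background correction with log2(intensity + 16), a normexp offset of 16, scaling to a common median, cyclic loess, the authors' value table, leaving out dim probes (mean below the 40th percentile), the mean of a gene's probes, sample weights, 1 variance per tissue, thresholds of 2-fold or of an adjusted p of 0.01, each kind of muscle alone as reference, 2 groups in place of 4, each tumour type alone, all samples in the fit, and leaving out each profile in turn. Others were chosen after seeing the data: all arrays as separate samples, near-identical arrays as a random block, leaving out E3 and R5 together, only the arrays of lower or of higher background, the side of that background split as a term, and all probes. The array medians fall into a set of 12 from 60.77 to 69.1 (all muscle and ERMS 1 to 6) and a set of 12 from 73.62 to 83.17 (ERMS 7 and 8 and all ARMS); the files and labels name no chip or batch, so the planned block by chip was not run.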

Results

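Gene expression was measured in 24 resected human tissue samples on bead arrays: 3 of skeletal muscle, 3 of adjacent muscle, 8 of ERMS and 10 of ARMS. After near-identical arrays were averaged, 12 profiles remained, and n below counts profiles. Levels are normalised log2 intensities; the median over all genes was 6.44 and the 95th percentile 10.04, so values near 6 lie at the background. The small number of arrays limits the precision. The labels do not say whether samples come from separate donors, so p-values measure only the spread between these samples. In RMS versus muscle, S1 is the only profile of its group, so its gap to adjacent muscle does not enter the error. That fit assumes that S1 varies like the other groups. The SDs printed for muscle do include that gap, so they can be wide beside a small SE. For COL1A1 the muscle SD was 2.53 and the SE of the difference 0.51. The series sets normal muscle against RMS, and ARMS against ERMS.

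RMS against muscle asks which genes separate the tumours from the tissue type they resemble. Genes of mature fibres fell, the oxygen store and contractile genes among them. MB, which encodes the oxygen store myoglobin, fell by 7.13 (SE 1.59, adjusted p = 0.0213), from 14.61 ± 0.056 (SD, n = 3) in muscle to 7.48 ± 2.52 (SD, n = 9) in RMS. MYOZ1, a Z-disc anchor of calcineurin, fell by 6.67 (SE 0.913), and MYH7, the slow myosin heavy chain, by a log2 difference of -6.55 (SE 1.63, adjusted p = 0.033). TCAP, which caps titin, differed by -6.50, MYBPC1, the slow myosin-binding protein, by -6.39, MYL3 and MYL2, slow myosin light chains, by -6.38 and -6.26, and TNNC1, the slow troponin C, by -6.25, with adjusted p from 0.00638 to 0.0423. All 9 tumours lay below all 3 muscle profiles for each of these 8 genes, which the rule that picked them required. The fast heavy chains MYH1 and MYH2 differed by -5.39 (adjusted p = 0.000663) and -6.02 (adjusted p = 0.013). Tumour levels reached the background for MYH1 (6.07 on average), for MYH2 in 7 of 9 tumours (below 6.2) and for several of the other genes, so the floor of the scale limits how large these differences can be. Without the skeletal muscle profile S1, MYOZ1, MYL3 and MYH1 stayed past the test, and the other 7 genes did not, with differences from -5.95 (TNNC1) to -7.14 (MB).

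The adult sarcomere list was lower as a whole. Of its 42 measured genes 38 were lower over all genes tested and 39 adjusted over the list alone, with a median log2 difference of -3.90. Camera's adjusted p was 5.05e-29, and the call did not hold with an estimated correlation (adjusted p = 0.124 with an estimated correlation), while fry gave 0.00105. Excitation-contraction coupling, the calcium machinery of the fibre, had 16 of 23 genes lower (18 adjusted over the list alone, 1 higher), with a median of -1.99 and an adjusted p = 0.12 with an estimated correlation. Its calcium store protein CASQ1 differed by -5.68 ± 0.735 (SE) and its calcium pump ATP2A1 by -4.97 ± 0.612 (SE).

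Energy metabolism of muscle was lower along several routes. All 11 genes of the phosphagen and oxygen store list were lower, with a median of -4.91. CKM, the cytosolic creatine kinase, differed by -5.45 (SE 1.12, adjusted p = 0.0152), its mitochondrial relative CKMT2 by -5.39, and ADSS1, an enzyme of the purine nucleotide cycle, by -4.44. Glycogen and glycolysis had 17 of 25 genes lower (21 adjusted over the list alone, 1 higher; median -2.08), with PGAM2, the muscle phosphoglycerate mutase, at -5.11 and FBP2, the muscle fructose bisphosphatase, at -2.42 ± 0.146 (SE). Fatty acid oxidation had 18 of 24 lower (23 adjusted over the list alone; median -1.65), among them the fatty acid carrier FABP3 at -2.19 and the acyl-CoA synthetase ACSL1 at -2.10. Oxidative phosphorylation had 36 of 66 lower (55 adjusted over the list alone, 1 higher; median -1.11), including the complex I subunit NDUFA8 at -1.39 and the complex IV subunit COX7B at -1.64. The TCA cycle had 9 of 17 lower (16 adjusted over the list alone; median -1.02), with citrate synthase, CS, at -1.16 and DLST, a subunit of oxoglutarate dehydrogenase, at -0.64. Without S1, FBP2 differed by -1.34 and FABP3 by -1.29, both past the test, while CKM (-5.25), COX7B (-1.15), CS (-0.73) and DLST (-0.41) no longer passed it. Over 28 refits the median of glycogen and glycolysis ran from -2.42 to -1.34 and that of oxidative phosphorylation from -1.4 to -0.728. For these 5 lists the adjusted p was 0.12 with an estimated correlation, and fry's adjusted p lay at or below 0.00141.

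Genes of dividing cells rose. CDC20, which activates the anaphase-promoting complex, rose by a log2 difference of 3.49 (SE 0.645, adjusted p = 0.0099), from 7.33 ± 1.95 (SD, n = 3) to 10.82 ± 0.66 (SD, n = 9). The transcription factor E2F2 rose by 2.87 (SE 0.598) and the condensin subunit NCAPG by 2.59 (SE 0.394). In S1 and A2 both lay near the background (6.15 and 6.34 for E2F2, 6.04 and 5.97 for NCAPG). The floor of the scale therefore limits these differences too. TOP2A, a topoisomerase of dividing cells, rose by 2.99 (adjusted p = 0.0179), the kinetochore protein SPC24 by 2.35, and the replication proteins MCM10 and MCM5 by 1.72 and 1.43. CCND2, a cyclin of the G1 phase, rose 12.8-fold (adjusted p = 0.0145), from 8.97 ± 2.38 to 12.65 ± 0.73, and its partner kinase CDK4 2.92-fold (adjusted p = 0.00586), while CDK2 rose 2.10-fold. Without S1, only NCAPG, MCM10 and MCM5 of these 10 genes stayed past the test: CDC20 differed by 2.44 (adjusted p = 0.131), E2F2 by 2.32, SPC24 by 1.75, TOP2A by 1.99, CDK4 by 1.12 and CDK2 by 0.98, and the log2 difference of CCND2 moved from 3.68 to 2.36. Mitosis had 33 of 53 genes higher (48 adjusted over the list alone; median 1.28; adjusted p = 0.124 with an estimated correlation), and all 53 differences were positive. DNA replication had 19 of 39 higher (31 adjusted over the list alone; median 1.05; adjusted p = 0.12 with an estimated correlation). Among cyclins, kinases and inhibitors 7 of 27 were higher and 1 lower (10 and 2 adjusted over the list alone), with an adjusted p = 0.414 with an estimated correlation, and camera's call of that list was lost without S1.

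Other genes that rose have no single theme. Among called genes with every tumour above every muscle profile, the largest increase was that of KANK4, a regulator of the actin skeleton. It rose by 4.12 (SE 0.652, adjusted p = 0.00548), from 7.01 ± 1.13 (SD, n = 3) to 11.14 ± 1.04 (SD, n = 9). FSCN1, which bundles actin in cell protrusions, rose by 3.61 (SE 0.507, adjusted p = 0.00349), and its 9 tumour values spread by an SD of only 0.288. MIR503HG, the host transcript of a microRNA cluster, rose by 3.40, the membrane protein gene TRO by 2.61, and NT5DC2, of the 5'-nucleotidase family, by 2.51. The imprinted genes PEG3, MEG3 and IGF2 rose by 4.0 (adjusted p = 0.0171), 3.39 (adjusted p = 0.00797) and 2.91 (adjusted p = 0.028); these were the 3 members higher, also adjusted over the list alone, of 15 imprinted growth genes (median 0.70; adjusted p = 0.376 with an estimated correlation). FGFR4, a growth factor receptor of muscle precursors, rose by 2.90 (adjusted p = 0.0412) as the only member past the test of 28 PAX3/7-FOXO1 associated genes, of which 0 passed adjusted over the list alone (median 0.89; adjusted p = 0.648 with an estimated correlation). COL1A1 and COL1A2, the chains of type I collagen, rose by 2.53 and 2.05 in a fibroblast and matrix list with 4 of 23 higher (5 adjusted over the list alone; median 0.73; adjusted p = 0.611 with an estimated correlation). The other COL1A2 probe, with a mean level of 10.59, gave only 1.32 (SE 0.769). Without S1, only TRO stayed past the test: KANK4 differed by 3.47 (adjusted p = 0.0503), MIR503HG by 2.69, NT5DC2 by 2.02, FSCN1 by 2.15, PEG3 by 2.51, MEG3 by 2.16, IGF2 by 1.78, FGFR4 by 1.58, COL1A2 by 0.83 and COL1A1 by 0.46, and these 3 lists lost camera's call.

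Chromatin regulators had 11 of 30 genes higher (18, and 1 lower, adjusted over the list alone), with a median of 1.03 and an adjusted p = 0.12 with an estimated correlation. The deacetylase HDAC2 rose by 1.28 and the corepressor TRIM28 by 1.19, whereas EZH2, the methyltransferase of Polycomb, lay 1.07 higher in RMS without passing the test (adjusted p = 0.0555), although all 9 tumours lay above all muscle profiles; it passed in 8 of 31 other settings, among them without A1 or without E3, with adjusted p from 2.17e-05 to 0.279 over all of them. Ribosome biogenesis had 5 of 23 higher (9 adjusted over the list alone; median 0.37; adjusted p = 0.138 with an estimated correlation), with nucleolin, NCL, at 0.96 and POLR1B, a subunit of RNA polymerase I, at 0.48. Cytosolic ribosomal proteins had 6 of 42 higher (16 adjusted over the list alone; median 0.49; adjusted p = 0.376 with an estimated correlation), led by RPL11 at 0.95 and RPL18 at 0.79. Without S1, HDAC2 differed by 0.97, TRIM28 by 0.72, NCL by 0.92, POLR1B by 0.23, RPL11 by 0.73 and RPL18 by 0.43, none of them past the test. Over 28 refits the median of ribosome biogenesis ran from 0.203 to 0.59 and that of cytosolic ribosomal proteins from 0.231 to 0.733. Hedgehog had only GLI3, a transcription factor of that pathway, higher of 13 (0.96, also adjusted over the list alone; median 0.23; adjusted p = 0.37 with an estimated correlation), and without S1 it no longer passed (0.94). Of the lists of other cell types, camera called endothelial, adipocyte and erythroid lower, and fibroblast and matrix higher. The endothelial list had 1 of 18 lower (0 adjusted over the list alone; median -0.46; adjusted p = 0.376 with an estimated correlation), the junction protein ESAM at -1.19 (-1.03 without S1, not past the test). Adipocyte genes had 4 of 13 lower (7 adjusted over the list alone; median -0.32; adjusted p = 0.224 with an estimated correlation), among them the lipid droplet proteins CIDEC at -0.91 and PLIN1 at -0.49. Both values rested on S1: CIDEC stood at 7.97 in S1 against 6.26 in A1 and 6.56 in A2, and without S1 the differences were -0.13 and -0.14, neither past the test. Erythroid genes had 3 of 9 lower, also adjusted over the list alone (median -0.56; adjusted p = 0.37 with an estimated correlation), with ALAS2, the haem synthesis enzyme of red cells, at -1.64 and the globin HBD at -0.57. These rested on S1 too, where ALAS2 stood at 9.65 against 5.94 in A1 and 6.5 in A2; without S1, ALAS2 turned to 0.0721 and HBD moved to -0.060, neither past the test. Immediate-early and heat shock genes had 1 of 19 lower (3 adjusted over the list alone; median -0.51; adjusted p = 0.648 with an estimated correlation), the transcription factor EGR3 at -0.47 (-0.29 without S1, not past the test). The Hedgehog, adipocyte, erythroid, and immediate-early and heat shock lists lost camera's call without S1. These losses differ in size. Over all 28 refits the Hedgehog median stayed at or above 0.167. The adipocyte and erythroid medians shrank to as little as -0.0777 and -0.0431, and that of immediate-early and heat shock genes turned to as high as 0.138.

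The regulators that set up muscle identity did not move together. MYF6, the factor of mature fibres, fell by 3.76 (SE 0.608, adjusted p = 0.00593), from 10.59 ± 1.04 to 6.83 ± 0.80. MYOD1 and MYOG, which start muscle differentiation, lay 1.20 (SE 0.571, adjusted p = 0.254) and 1.60 (SE 0.681, adjusted p = 0.194) higher in RMS, within the spread. MYF5, PAX3 and PAX7, factors of muscle precursors, differed by 0.28, 0.17 and 0.08, and the embryonic heavy chain MYH3 by 0.72 (adjusted p = 0.569), which turned to -1.20 without S1. The myogenic regulators list had 1 of 24 genes higher and 2 lower, also adjusted over the list alone (median 0.12, camera adjusted p = 0.987; its mean was -0.04), and developmental muscle had 1 of 13 higher, also adjusted over the list alone (median 0.72, camera adjusted p = 0.288). The direction of the developmental muscle list rested on the reference: its median was -0.125 without S1, -0.011 without A2 and 1.45 without A1, where camera called it higher (adjusted p = 0.0155). The remaining lists did not pass camera. Notch had 1 member higher and 1 lower, YAP-TEAD and Wnt had 2 lower each, IGF axis 1 higher, proteoglycans 1 higher and 1 lower, Schwann cell 1 higher, hypoxia 2 lower, and neutrophil, interferon response and pericyte and smooth muscle 1 lower each. RAS-MAPK output, neuronal, cancer-testis antigens, MHC class I presentation, T cell, B cell and plasma cell, macrophage and myeloid, and epithelial had 0 members past the limma test, with medians from -0.16 (MHC class I presentation) to 0.24 (B cell and plasma cell).

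Over all 18775 genes limma called 657 higher and 1240 lower in RMS, 434 and 762 of them by at least 2-fold. In 674 genes every tumour lay above every muscle profile and in 846 below, where random grouping gives 0.909% of genes in both directions together; 1042 of these were called. Of the 41 lists camera called 10 higher and 11 lower, fry called 15, and camera with an estimated correlation called 0 (11 at an unadjusted p under 0.05).

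These counts rest on the muscle profile S1: without it 44 genes were higher and 284 lower, and without A2 196 and 696; of 58 named genes called, 17 stayed past the threshold without S1 and 37 without A2, and each of the 21 lost without A2 was also lost without S1; 8 of the 21 lists lost camera's call without S1. A1 lay within the tumour range for several genes that rose, among them MEG3 at 12.2, CCND2 at 12.12, TOP2A at 9.56, PEG3 at 11.12 and COL1A1 at 12.64, and among the 12 arrays of lower background, which hold all muscle and most ERMS arrays, limma called 0 genes (3247 at an unadjusted p under 0.05). With the side of the background split as a term, 91 genes were higher and 384 lower. Of the 58 named genes, 20 then stayed past the threshold. All muscle lies on the lower side and all ARMS on the higher, so only ERMS profiles set that term. ERMS alone against muscle, without the term, already gave 147 and 382. All 1897 called genes kept their sign with the term and in the fit of the lower side. Whether the background lowers the counts cannot be told from these fits.

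**Figure D1:**
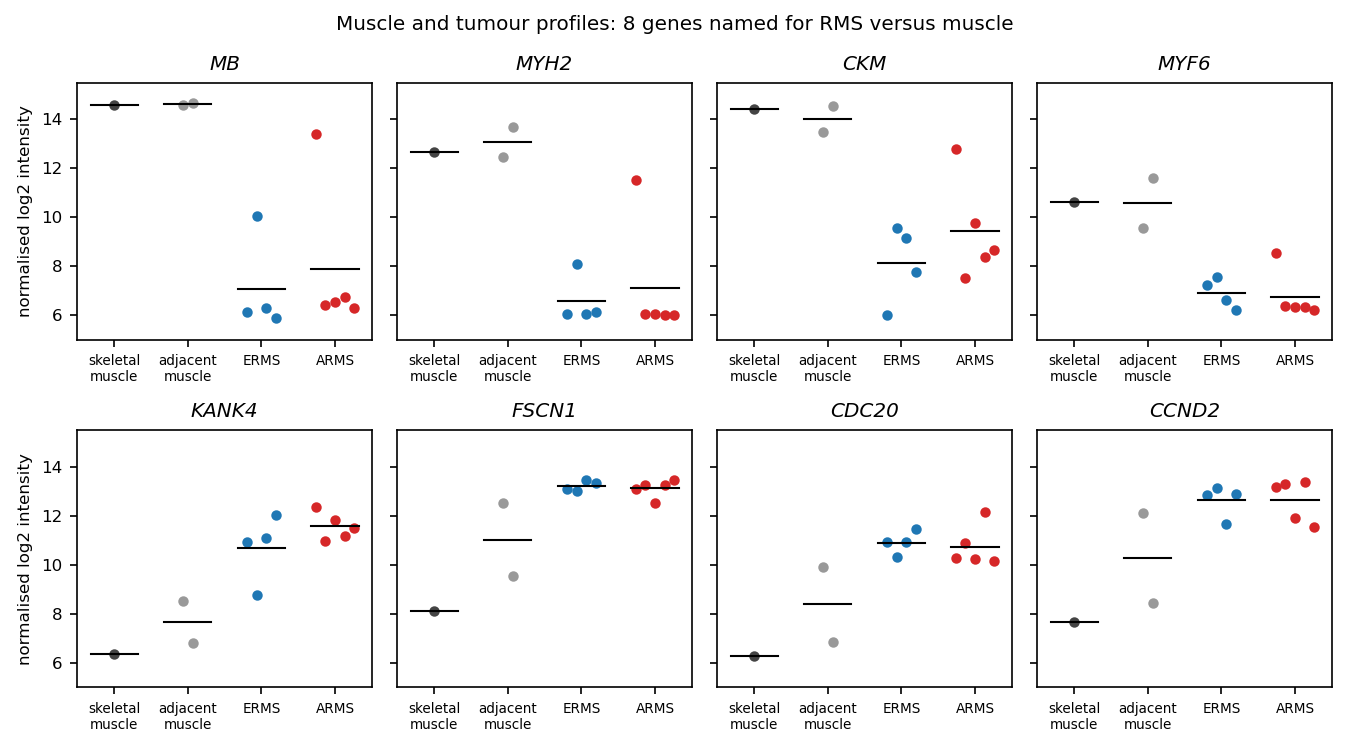
Normalised log2 intensity (vertical axis) of 8 genes in the 12 profiles by group (horizontal axis); each point is a profile and each line the mean of a group. All tumours lie below all muscle for MB, MYH2, CKM and MYF6, with R1 the highest tumour (MB 13.38). They lie above all muscle for KANK4, FSCN1 and CDC20. The rule that picked MB, KANK4, FSCN1 and CDC20 required this separation. For CCND2 the adjacent profile A1 (12.12) lies inside the tumour range.

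**Figure D2:**
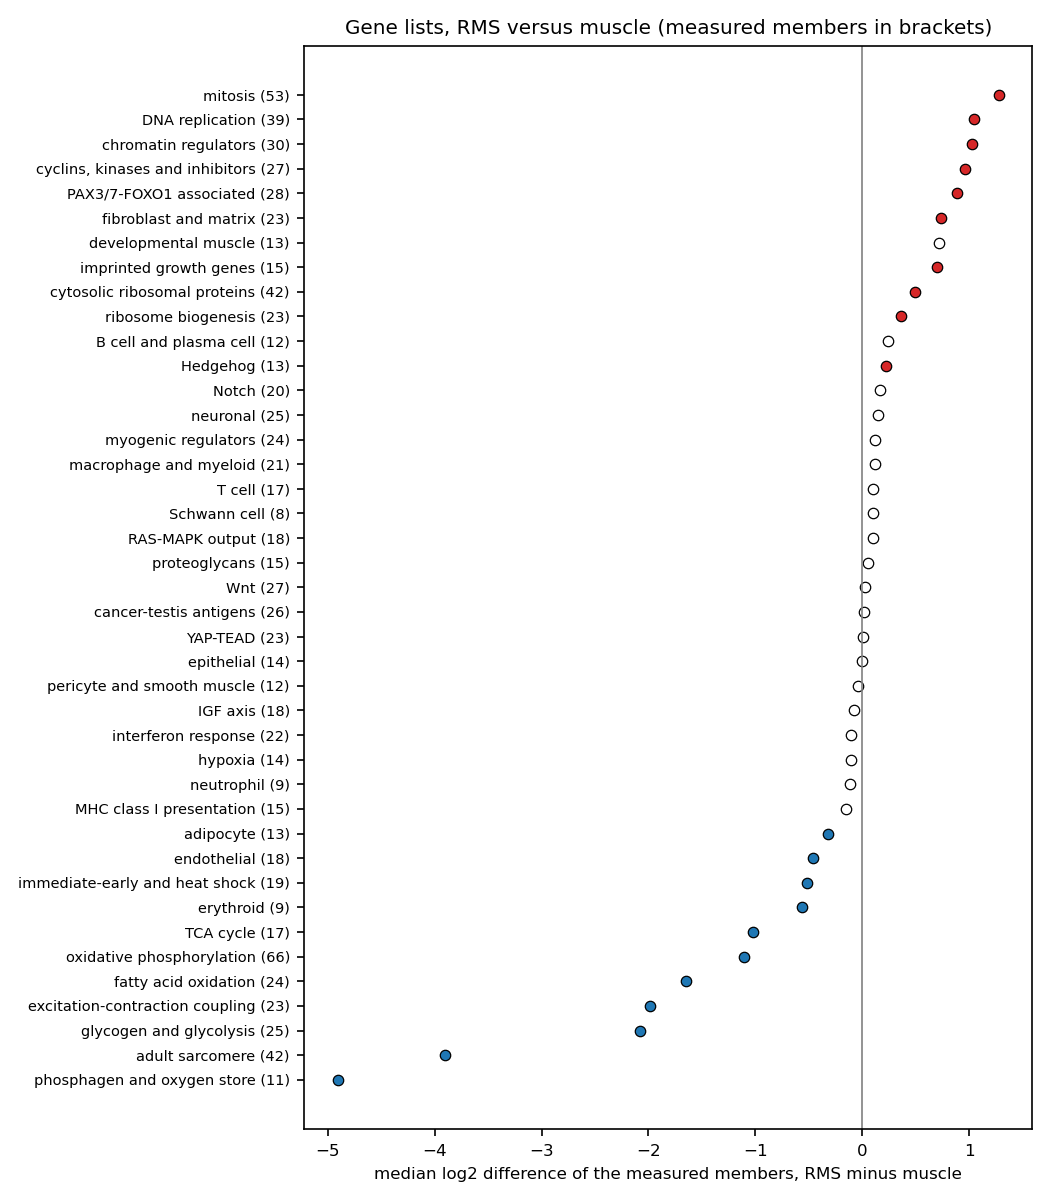
Median log2 difference, RMS minus muscle (horizontal axis), of the measured members of each of the 41 lists (vertical axis; number of members in brackets). Filled points passed camera at the preset correlation, red higher and blue lower, and open points did not; medians run from -4.91 (phosphagen and oxygen store) to 1.28 (mitosis).

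ARMS against ERMS asks what separates both tumour types. Many ARMS carry a fusion of PAX3 or PAX7 with FOXO1, a strong transcription factor, and its target genes were named in advance. These genes varied more within each label than between the labels. TFAP2B, a neural crest transcription factor and a direct fusion target, lay at 8.42 ± 2.61 (SD, n = 4) in ERMS and 8.74 ± 1.86 (SD, n = 5) in ARMS, a difference of 0.32 (SE 1.34, adjusted p = 0.999). By profile, TFAP2B stood at 10.64 in E3, 10.70 in E4, 10.85 in R5, 9.58 in R2, 9.41 in R1 and 7.83 in R3, but near the background in E1 (6.10), E2 (6.22) and R4 (6.02).

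Among the other fusion targets, OLIG2 and PIPOX stood near the background in the same 3 profiles and CDH3 was lowest there, while MYCN and FGFR4 did not follow that order. CDH3, the adhesion protein P-cadherin, differed by 0.90 (SE 0.776) between the labels, and stood at 9.22 in E3 and 9.0 in E4 against 6.42 in E1 and 7.14 in R4. OLIG2, a neural lineage factor, differed by -0.14 (SE 1.09), with 10.18 in E3, 10.17 in E4 and 9.91 in R5, against 6.16 in E1, 6.18 in E2 and 6.31 in R4. PIPOX, a peroxisomal oxidase, differed by 1.17 (SE 0.925) and reached 10.04 in R2, 9.54 in R5 and 9.10 in E3, against 6.13 in R4. ALK, a receptor kinase, differed by 0.27 (SE 0.917), with its highest value, 10.41, in E4. MYCN, a growth-driving transcription factor, differed by 0.75 (SE 0.869) and was lowest among the tumours in E2 (7.24) and E1 (7.27), but R4 (9.10) lay above R2 (8.26). NOS1, a nitric oxide synthase used as a marker of ARMS, was at the background in every tumour profile (6.24 in ERMS and 6.12 in ARMS on average). FGFR4 stood at 10.47 ± 0.86 in ERMS and 11.11 ± 0.84 in ARMS, a difference of 0.64 (SE 0.517), with R4 (10.91) above E4 (10.59) and R3 (9.77); the dimmest of its 3 probes gave -0.013. CNR1, a cannabinoid receptor, differed by 0.60 (SE 0.571).

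The genes named in advance as candidates for ERMS behaved likewise. FBN2, a fibrillin of the embryonic matrix, lay 3.46-fold higher in ERMS than in ARMS (log2 difference -1.79, SE 1.15, adjusted p = 0.999), and this rested on E1 (11.14) and E2 (12.13), while E3 (7.24) and E4 (6.81) lay with most ARMS profiles and R4 reached 9.01. HMGA2, a chromatin protein of embryonic cells, differed by -0.15 (SE 0.0708) near the background, and EGFR, a growth factor receptor, by -0.20 (SE 0.302). The myogenic factors MYOG and MYOD1 differed by 0.72 (SE 0.604) and 0.17 (SE 0.469). PAX3 (6.16 in ERMS, 6.28 in ARMS) was at the background in both, PAX7 differed by -0.07 and FOXO1 by 0.14; the probes do not read the fusion transcript as such. CCND2 and CDK4 were alike, with differences of 0.02 and 0.01. The adjusted p was 0.999 for each of these genes.

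The lists gave the same picture. PAX3/7-FOXO1 associated genes were higher in ARMS by camera (28 genes, median 0.61, 24 of 28 positive, adjusted p = 0.00824), with adjusted p = 0.893 with an estimated correlation. All ARMS arrays but only 2 of 8 ERMS arrays lie on the side of higher background, and with only those arrays, or with the side as a term, its median turned to -0.069. Both refits set ARMS against only E3 and E4, the ERMS profiles that stood high in this list. The turn therefore cannot be put down to the background. The level of this list was -0.90 in E1 and in E2 and -0.39 in R4, against 0.72 in E3, 0.65 in E4, 0.78 in R1, 0.73 in R2, 0.42 in R3 and 0.72 in R5. RAS-MAPK output, genes that report signalling through RAS, was lower in ARMS (18 genes, median -0.42, 17 of 18 negative, camera adjusted p = 0.0217), with adjusted p = 0.893 with an estimated correlation. Its median turned to 0.147 with only the arrays of higher background or with the side as a term, again against only E3 and E4 of the ERMS profiles. Immediate-early and heat shock genes, which respond to tissue handling, were likewise highest among the tumours in E1 and E2, with levels of 0.39 in E1 and 1.57 in E2 against -0.94 in E3, -0.81 in E4, -0.73 in R4 and -0.95 in R5, where RAS-MAPK output stood at 0.88 and 1.27 against -0.24, -0.68, -0.53 and -0.19. That list did not pass between the labels (median -0.28, 15 of 19 negative, camera adjusted p = 0.292), and its median turned to 0.706 in the same refits. Chosen after their values were seen, SPRY4, a feedback inhibitor of that pathway, stood at 10.85 in E1 and 11.69 in E2 against 7.91 in E3, and the transcription factor ETV5 at 9.95 and 10.62 against 6.89 in E4. Adult sarcomere (median 0.40, camera adjusted p = 0.0134), excitation-contraction coupling (0.22, 0.0344), glycogen and glycolysis (0.22, 0.0344) and endothelial genes (0.37, 0.0218) were higher in ARMS. For these 4 lists too the adjusted p was 0.893 with an estimated correlation, and 0 members of the 6 lists passed. The other 35 lists did not pass camera; the nearest was cancer-testis antigens (median -0.04, camera adjusted p = 0.057), where PRAME, chosen after its values were seen, differed by -2.00 (list-alone adjusted p = 0.123). Adjusted over the list alone, FZD7, a Wnt receptor, was lower in ARMS (-0.63, adjusted p = 0.0329), as was ERAP1, which trims antigen peptides (-0.30, adjusted p = 0.0485), and 0 genes of the other lists passed. That adjustment was made separately in each of 41 lists, so a few such calls can arise by chance. Over all genes the smallest adjusted p by limma was 0.999.

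Over all 18775 genes limma called 0 higher and 0 lower in ARMS, with 761 at an unadjusted p under 0.05 where 938.8 are expected by chance and a smallest adjusted p of 0.999. Every ARMS profile lay above every ERMS profile in 145 genes and below in 208, where random grouping gives 1.59% of genes in both directions together. Both counts together lie near that share, and 0 of these genes were called. Counting all 18 tumour arrays as separate samples gave 377 higher and 408 lower, and near-identical arrays as a random block gave 8 and 28. The camera calls rested on single profiles: without E1 or without R1, 0 lists were called, and without R1 adult sarcomere had a median of -0.08.

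**Figure D3:**
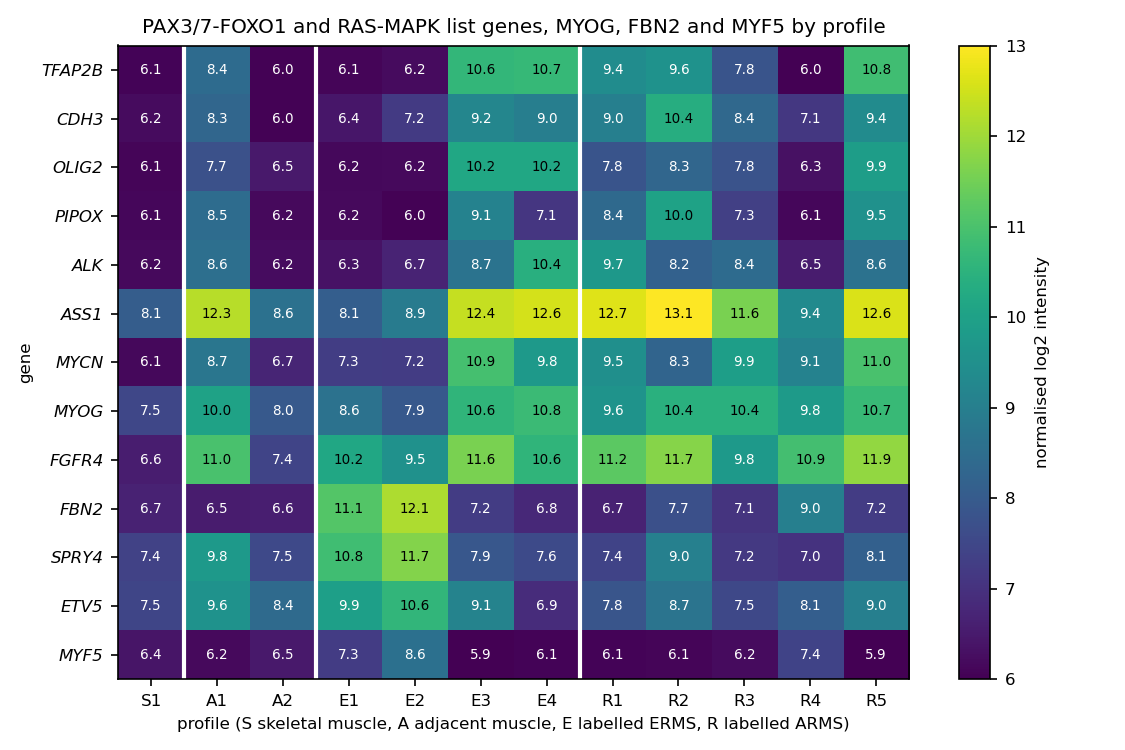
Normalised log2 intensity (colour and printed value) of 13 genes (vertical axis) in the 12 profiles (horizontal axis; white lines part the groups). TFAP2B, CDH3, OLIG2, PIPOX, ALK and ASS1 are high in E3, E4, R1, R2, R3 and R5 for most genes and low in E1, E2 and R4, while FBN2, SPRY4 and ETV5 are highest in E1 and E2; ASS1, SPRY4 and ETV5 were chosen after their values were seen.

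Adjacent against skeletal muscle bears on whether both can serve as the reference. Embryonic and matrix transcripts lay higher in both adjacent profiles than in S1. MYH3 stood at 12.93 in A1 and 10.01 in A2 against 7.64 in S1, and COL1A1 at 12.64 and 10.97 against 7.67. Genes of division were high in A1 only: TOP2A reached 9.56 in A1 against 6.27 in A2 and 5.92 in S1, and CDC20 9.91 against 6.85 and 6.29. Mature fibre genes were present in all 3 profiles but lower in A1: the adult sarcomere level was 1.99 in A1 against 3.48 in A2 and 3.35 in S1, and that of phosphagen and oxygen store 2.27 against 3.87 and 4.32. MYL3 stood at 11.36 in A1 against 13.67 in A2 and 14.02 in S1, and MYH1 at 9.04 against 11.17 and 12.82. MB lay near the top of the scale in all 3 (14.57, 14.68 and 14.60), where a difference would show little.

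By limma 0 genes passed in this comparison (438 at an unadjusted p under 0.05), with 1 profile against 2, so the values by profile stand without a test and the list calls describe these 3 profiles only. Camera called 15 lists higher in adjacent muscle, among them fibroblast and matrix (median 0.90), developmental muscle (1.51), mitosis (0.60), chromatin regulators (0.42), macrophage and myeloid (0.36), MHC class I presentation (0.31), DNA replication (0.29), PAX3/7-FOXO1 associated (0.99) and proteoglycans (0.38), and 10 lower, among them oxidative phosphorylation (-0.60), fatty acid oxidation (-0.93), glycogen and glycolysis (-0.80), phosphagen and oxygen store (-1.25), adult sarcomere (-0.55), erythroid (-0.96) and immediate-early and heat shock (-0.53). With an estimated correlation 0 lists passed (smallest adjusted p 0.795, 0 at an unadjusted p under 0.05), and fry called 0 (1 at an unadjusted p under 0.05). Chosen after their values were seen, FOS, a stress-response factor, stood at 12.59 in S1 against 7.79 in A1 and 8.92 in A2, and its relative FOSB at 10.45 against 7.22 and 7.42. CHRNA1, the receptor subunit of the nerve contact, stood at 8.48 in S1 against 11.52 and 11.09. Many of these medians rested on A1. Without it, in a fit that also pooled the spread over all groups, adult sarcomere turned to a median of 0.13. Mitosis fell to 0.068, chromatin regulators to 0.095, DNA replication to 0.028 and PAX3/7-FOXO1 associated to 0.115. Macrophage and myeloid fell to 0.121 and proteoglycans to 0.22, and phosphagen and oxygen store shrank to -0.39. Fibroblast and matrix (0.82) and developmental muscle (0.34) stayed higher without A1. Oxidative phosphorylation (-0.39), fatty acid oxidation (-0.41), glycogen and glycolysis (-0.32), adipocyte (-0.17), erythroid (-0.71) and immediate-early and heat shock (-0.74) stayed lower, the last also without A2 (-0.62). MHC class I presentation and proteoglycans kept medians at or above 0.203 and 0.19 in every setting. The fits without A1 or A2 also changed how the spread was estimated, so changes in camera's calls there cannot be put down to the profile alone.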

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

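The rule of this part was fixed before the data were examined. The profiles it was applied to were formed afterwards, and many of the named genes were picked from these data. A total of 77 named genes and 41 lists were looked at in the ERMS and the ARMS profiles. A value is given where the gap between the highest or lowest profile and its neighbour is too wide for the range of the group by Dixon's test. This held in 33 of 236 groups, where 11.8 are expected by chance. No explanation was tested for these values.

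The ARMS profile R1 held 15 of them, 13 genes and 2 lists, as the highest of 5 profiles for genes of mature fibres. MB stood at 13.38 (next 6.75), MYL2 at 13.9 (7.99), MYH7 at 13.61 (6.86), MYBPC1 at 12.46 (7.60), TNNC1 at 12.28 (8.35), TCAP at 11.56 (6.23), MYH2 at 11.53 (6.07), MYL3 at 10.95 (6.23) and MYOZ1 at 10.53 (6.83). CKMT2 stood at 9.33 (7.21), CASQ1 at 8.97 (6.16), MYF6 at 8.53 (6.36) and MYH1 at 7.17 (6.15). The adult sarcomere list stood at 1.36 in R1 against -0.94 in the next ARMS profile, and the phosphagen and oxygen store list at 1.25 against -1.45. These genes share the muscle programme, so they do not count as separate findings.

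The ERMS profile E2 was highest of 4 for several of the same genes at lower levels: MB at 10.03 (next 6.28), MYH2 at 8.09 (6.15), TCAP at 7.72 (6.10) and MYL3 at 7.41 (6.46). E2 was also highest for CS at 10.92 (10.48), COX7B at 8.90 (8.23), the red cell gene ALAS2 at 7.53 (6.10) and the neutrophil list at 0.484 (-0.098).

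The ARMS profile R3 was highest for the T cell list at 1.52 (next -0.12) and the B cell and plasma cell list at 1.40 (-0.04), and lowest for imprinted growth genes at -0.687 (0.13) and for RPL11 at 13.64 (13.91). Chosen after their values were seen, the T cell receptor component CD3D stood at 9.98 in R3 and the B cell receptor component CD79A at 10.68. The ERMS profile E4 was highest for the neuronal list at 0.997 (-0.017) and for HDAC2 at 10.48 (9.81), and E1 lowest for RPL18 at 14.14 (14.37). R4 was highest of the ARMS for MYF5 at 7.41 (6.20) and lowest for the pericyte and smooth muscle list at -0.644 (0.07), and R2 was highest for cyclins, kinases and inhibitors at 0.466 (0.11).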

How the results depend on the processing

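The alternatives named under the processing as added, from all arrays as separate samples to all probes, were chosen after seeing the data; the others were planned. No paired analysis was possible because the labels give no replicate numbers; the numbers used here only name samples in their order and pair none. Where no cause is named for a change, the cause was not tested. Not run were the block by chip (no chip is named), sample weights in adjacent versus skeletal muscle and that comparison without S1, its only skeletal profile.

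RMS against muscle gave 657 genes higher and 1240 lower. Within 1.5 times of both lay no background correction, an offset of 16, loess, the authors' values, no dim probes, mean probes, sample weights, 1 variance per tissue and 2 groups. A common median gave 310 and 655, the 2-fold limit 434 and 762, an adjusted p of 0.01 121 and 536, skeletal muscle alone as reference 383 higher, adjacent muscle alone 44 and 284, ERMS alone 147 and 382, and ARMS alone 112 and 354; the last 4 use fewer profiles. Leaving out single profiles gave 44 to 815 higher and 284 to 1473 lower, lowest without S1 (44 and 284) and then without A2 (196 and 696). All arrays as separate samples gave 3179 and 3001, near-identical arrays as a random block (correlation 0.688) 1960 and 1955, without E3 and R5 397 higher, the background side as a term 91 and 384, and only the 12 arrays of lower background 0 and 0 (3247 at an unadjusted p under 0.05, smallest adjusted p 0.109); that fit holds 3 muscle and 3 ERMS profiles. Every one of the 1897 called genes kept its sign with either other background step, a common median, loess and the authors' values, and 912 of them were called again with a common median. Of 58 named genes called, 43 stayed past the threshold with a common median, 54 with loess, 17 with adjacent muscle alone and 20 with the background side as a term. ALAS2 turned to 0.0721 without S1, where leaving out other profiles gave values down to -1.83 (without E2), and also to 0.0721 with adjacent muscle alone against -3.36 with skeletal muscle alone. EZH2, not past the test, passed it with an offset of 16, no dim probes, mean probes, sample weights, without A1, without E3, with all arrays and with the random block; MYOD1 and MYOG passed in the last 2 only, and MYH3 with all arrays and with skeletal muscle alone. No scaling moved the share of higher calls (34.6%) by over 10 points; it ran from 29.6% to 40.8%. No scaling moved the median of all genes by over 0.1; the largest was 0.0889, in ARMS versus ERMS with a common median.

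For the lists of RMS against muscle (10 higher, 11 lower by camera), adjacent muscle alone, and so leaving out S1, gave 5 higher; leaving out single profiles gave 5 to 11 higher and 8 to 12 lower. An estimated correlation gave 0 and 0, and fry 6 higher. Of the 21 lists called, 13 kept the call in every refit of camera at the preset correlation. The other 8 lost it without S1: cyclins, kinases and inhibitors, PAX3/7-FOXO1 associated, Hedgehog, imprinted growth genes, fibroblast and matrix, adipocyte, erythroid, and immediate-early and heat shock.

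ARMS against ERMS gave 0 genes in each planned setting, with smallest adjusted p from 0.484 (without E4) to 1, and in 0 to 0 without single profiles. All arrays as separate samples gave 377 higher and 408 lower, and near-identical arrays as a random block (correlation 0.708) 8 and 28, with E3 and R5 in 1 block. Its lists (5 higher, 1 lower) were 3 lower with a common median, 1 higher with loess, 3 higher and 2 lower with mean probes, 8 and 2 with all arrays, 2 lower without E3 and R5, and 3 higher and 0 lower both with only the 12 arrays of higher background and with the background side as a term; an estimated correlation gave 0 and 0, and so did fry. Leaving out single profiles gave 0 to 5 higher and 0 to 3 lower. Oxidative phosphorylation turned to 0.359 with a common median, adult sarcomere to -0.075 without R1 (up to 0.599 without R2), and B cell and plasma cell to -0.148 without R3 (up to 0.191 without E4). With only the arrays of higher background, or with the side as a term, PAX3/7-FOXO1 associated turned to -0.069, RAS-MAPK output to 0.147, fibroblast and matrix to 0.489 and immediate-early and heat shock to 0.706; both fits set R1 to R5 against E3 and E4 on that side.

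Adjacent against skeletal muscle gave 0 genes in its own fit. All samples in the fit gave 1 higher and 21 lower, leaving out A1 or A2, with the spread pooled over all groups, 2 to 50 higher and 17 to 152 lower, and all arrays as separate samples 259 and 257. In these fits S1 is assumed to vary like the other groups. Its lists (15 higher, 10 lower) were 2 to 12 higher and 6 to 9 lower without A1 or A2, and 0 and 0 with an estimated correlation and with fry. Without A1, adult sarcomere turned to 0.125 and cytosolic ribosomal proteins to -0.0491, and for DNA replication camera's direction turned, with a median of 0.0278; without A2 these medians were -1.39, 0.815 and 0.791. Signal over background limits every value near 6, since a gene there may change unseen: with the 40% dimmest probes left out, 780 genes were higher and 1298 lower in RMS.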

Other observations

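Some tumour profiles carried whole sets of transcripts of their own. The tests of repeated arrays, of dilution in R4, of wrong labels and of the share of tumour RNA in A1 were chosen only after the result was seen. In E4 the neuronal genes ELAVL3, an RNA-binding protein of neurons, and STMN2, which shapes growing axons, stood at 10.65 and 11.81, and STMN2 also at 10.66 in R1; all genes named in this paragraph were chosen after their values were seen. H19, an imprinted noncoding RNA, stood at 14.03 in E3 and 14.5 in R5 but between 7.95 and 9.44 in E1, E2 and E4. NNAT, an imprinted gene of the developing brain, was high in E1 (13.67), E2 (13.46), E4 (13.45), R2 (12.39) and R4 (12.19) and below 7.3 in the other tumour profiles. PRAME, a cancer-testis antigen, stood at 10.09 in E1 and 9.16 in E2 and at 7.84 or less in every other profile. The sarcomeric actin ACTC1 and the embryonic light chain MYL4 were high in A1 (13.19 and 12.06), as in most tumours.

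Immune and handling genes differed between profiles as well. R3 was also highest for MHC class I presentation (1.21) and for macrophage and myeloid genes (0.977), and HLA-DRA, an antigen-presenting molecule, stood there at 13.03. E4 came next for T cell (0.598) and B cell and plasma cell genes (0.832). Immediate-early and heat shock genes were highest in E2 (1.57), where FOSB stood at 12.63, and in S1 (1.08).

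Sets of near-identical arrays run through the series. Inside a set at most 0.424% of bright genes differed by over 2-fold, while different tumour profiles differed in at least 9.42%, and before any normalisation the lowest correlation inside a set was 0.9858, above every pair of different profiles (at most 0.9595), which argues against the normalisation as the source. Repeated profiling of 1 specimen or RNA is consistent with this, and the labels do not say so. E3 (ERMS) and R5 (ARMS) differed in 0.553% to 0.681% of bright genes, beyond the range inside the other sets and far below that of different tumours, so 1 specimen under both labels and 2 closely related specimens cannot be told apart. Neither profile can then be read as independent evidence for its label.

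The adjacent profile A1 carried tumour-associated genes beside mature fibre genes. Outside the muscle lists, 17 of 27 PAX3/7-FOXO1 associated genes lay over 1 log2 unit above both S1 and A2 in A1 (median 1.39), up to 3.66 for ASS1. RNA of R1, the tumour nearest to A1, is argued against as the whole source: the 15 genes private to R1 that also lie above muscle rose in A1 by a median of only 0.164, and their levels allow a median share of 13.2% of R1 RNA (quartiles 3.69 to 19.9) whatever the muscle part holds, where the fusion-associated genes need 53.3% (40 to 90.3). For RNA of any single tumour profile the same shares are apart for 6 of the 8 profiles (E3 and R5 taken as 1). For E1, E2 and R4 among them, the needed share rests on only 2, 1 and 8 genes. These profiles are low in the list, so high needed medians (212%, 330% and 121%) were given in advance. The quartiles overlap for E3 and R5 (9.93% allowed, 2.25 to 22.8, against 48.7% needed, 17.9 to 83.9). For R2 they overlap as well (9.48%, 3.06 to 21.9, against 49.3%, 21.8 to 114). RNA of E3 and R5 or of R2, RNA of a tumour not measured here and regenerating fibres alone therefore cannot be told apart. For the last, the R1 genes outside muscle lists (median -1.46) are mostly muscle genes too.

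The PAX3/7-FOXO1 associated genes crossed the tumour labels: the highest ERMS profile lay 1.11 above the lowest ARMS profile, 2 of 4 ERMS profiles lay above the lowest ARMS and 2 of 5 ARMS below the highest ERMS. TFAP2B, CDH3 and OLIG2 differed by a median of only 0.241 between the E3 arrays on either side of the background split. These arrays share a profile because they are alike, so a large difference was unlikely from the start. The E3 array of lower background stood at 10.49, 9.34 and 10.12 for these genes. E1, all of lower background too, stood at 6.10, 6.42 and 6.16. For these 3 genes the background difference alone is therefore argued against as the source of the crossing. Dilution by muscle or immune cells in R4 is argued against as well, since its mitosis genes were the highest of the 5 ARMS (0.43 above the mean of the others) and its T cell (-0.275) and myeloid levels (-0.542) the lowest; its adult sarcomere level (-1.38) lay between those of R5 (-0.937) and R2 (-1.53), and its gap to the mean of the others, -0.717, shrinks to -0.043 without R1. Dilution was not examined in R3 (0.42), which also lay below the highest ERMS profile and was highest for T cell genes (1.52). Wrong labels on whole profiles may explain the crossing, but the measure used for this was the crossing itself with the likeness of E3 and R5. It could not have come out otherwise and adds no support. E3, which the counts include, cannot be read as independent evidence for its label. ARMS without the fusion could account for R4 alone, which stays untested as the probes do not read the fusion; it does not reach E3 (0.72) and E4 (0.65), which lie at ARMS levels under the ERMS label.

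Other splits of the samples bear on chance. Of 100 splits of the 12 profiles into groups of 1, 2, 4 and 5, only the real one gave 1897 or more genes. The highest of the others gave 1339 and keeps the same muscle profiles together while moving profiles within muscle or within tumours. The highest with another muscle set gave 36. The splits argue against chance for RMS against muscle, but 100 of them cannot exclude it. For the 9 tumour profiles the real split gave 0 genes, so all 100 of 100 splits give as many by construction, which says nothing about chance. The highest other, E1, E2, R3 and R4 against the rest, gave 394 and the next 2. These profiles are the lowest tumours in the PAX3/7-FOXO1 associated list (-0.90, -0.90, 0.42 and -0.39, next E4 at 0.65). With E3, E4, R2 or R5 in place of R3, such splits gave at most 2. Whether a structure of the samples lies behind the 394 genes was not tested. With all arrays as separate samples, 34 of 100 splits of whole profiles gave at least the real 785 genes (highest 3330), so those calls may come from counting near-identical arrays as samples.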
